A study of Homo sapiens with 15 samples.

How the data were processed

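Peripheral blood B cells of 3 donors were cultured in X-vivo 10 medium, per the labels' protocols. They were left unstimulated or stimulated with an antibody against the B cell receptor for 24 h, with vehicle (DMSO), an inhibitor of BTK (BTKi) or an inhibitor of GSK3 (GSK3i) at 1 µM added 30 minutes earlier. GSK3i was given to unstimulated cells only. Libraries were made from 200 ng of total RNA isolated with RNeasy micro plus and a SMARTER mRNA-Seq kit, per the labels' protocols. The labels give classes of inhibitor and no compound names.

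The deposited file holds counts of reads per RefSeq transcript in 15 libraries, which the submitters' processing notes say were made from reads aligned to hg19 with STAR. Its version and the program that counted reads are not given in the sources used here. The table has 48104 transcripts of 25678 gene symbols, and each of its columns was matched to a label. Of 80 entries where a date stood in place of a gene symbol, 78 were named through their accession and 2 were left out; 97.7% of accessions were found in the RefSeq table at hand. That table is on GRCh38 and the counts are on hg19, so no coordinates are printed. Y-linked and X-inactivation genes (109) were left out before any test.

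For each gene the transcript with the highest total was kept, because transcripts of 1 gene share reads: 9491 genes had more than 1 transcript, and in 918 of them all transcripts had identical counts. Of 7135 genes with several transcripts and at least 150 counts, 1079 had a highest transcript over 1.5 times the lowest. This left 25570 genes. Of these, 70 had the same counts as another symbol, so their reads cannot be told apart. Reads of near-identical genes, such as the copies of CCL3 and CCL4, and of glycolysis and heat shock genes with many pseudogenes may be shared or lost. Where genes overlap on opposite strands, reads may be counted for either, since the sources do not say whether the libraries were stranded.

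Totals over all transcripts were 23 to 52.92 M per library, and after collapsing 10.86 to 24.59 M. Between replicates of a group, the chi-square per degree of freedom was 13.94 to 63.19, where counting noise alone gives 1, so replicates differed by more than counting noise. RNA45S5 took 1.19 to 2.48% of the collapsed counts. MALAT1 took 3.14 to 7.64% and differed with the groups: 5.09, 3.14 and 4.63% in anti-BCR vehicle libraries against 7.05, 7.64 and 7.18% with BTKi, and 7.41, 5.74 and 6.32% in unstimulated vehicle libraries.

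Analyses used R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0, and Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9. Genes were filtered with filterByExpr (minimum count 10) by group, which left 16346. Libraries were scaled with TMM, and all 15 were fitted in 1 edgeR quasi-likelihood model (robust) with a mean per group. Benjamini-Hochberg adjusted p under 0.05 counted as called. Fold changes of genes came from the edgeR model with its default prior count. A prior count of 2 was used for log2 CPM, from which principal components, the score of other cell types and changes within donors were taken. The SE is the absolute log2 fold change divided by the square root of F. The 7 comparisons were BTKi with vehicle in unstimulated and in anti-BCR cells, GSK3i with vehicle, GSK3i with BTKi, anti-BCR with unstimulated cells under vehicle and under BTKi, and the difference of the 2 BTKi effects. Groups, tests, gene lists and the rule for named genes were fixed before the data were examined.

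Of 30 gene lists written, 29 were tested with camera at an inter-gene correlation of 0.01, over the genes that passed the filter. Benjamini-Hochberg adjustment ran over the lists of a comparison. The list of mitochondrially encoded transcripts had 0 members in the table and could not be tested. "Adjusted over the list alone" means that p values of genes were adjusted among the members of that list. Where a list is given as a count of its members, the count is of genes called in the direction of the list, and a second count is of genes called in the other direction. The score of other cell types averaged the standardised log2 levels of 52 marker genes, 12 of which had at least 5 CPM in unstimulated vehicle libraries and 4 of which stand in another list as well.

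Genes are named by a rule. It takes up to 8 higher and 8 lower genes with the largest absolute log2 fold change per comparison (5 and 5 for the difference of effects, the stimulus under BTKi, and GSK3i against BTKi) among called genes with a mean of at least 5 CPM in the higher group and the same direction in all 3 donors. It adds up to 4 members with the smallest p in each list described, and BTK, GSK3A and GSK3B. Where fewer than 5 genes passed, the 5 with the smallest p are given as values that did not pass. Receptor segments of B and T cells, classical HLA genes, pseudogenes, antisense, read-through and small or unnamed RNAs were left out of the first part. A result for 1 gene that the rule names is not reported here.

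Replicate numbers stand for donors, per the labels, so they pair the libraries. Deviations from the group means correlated at 0.44 to 0.66 in all 30 pairs of libraries of the same donor and at -0.43 to -0.10 between donors, and 15 of 15 libraries correlated best with their own donor. The donor as a block was the alternative fit; it lowered the common dispersion from 0.0504 to 0.0112.

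The scripts were tested on simulated counts with 200 changed genes. For BTKi in unstimulated cells (16109 genes), the fit without the block recovered 30.3%, 55.4% and 79.7% of genes changed 1.5-, 2- and 4-fold, with 0 false calls, and the fit with the block 66.7%, 69.2% and 96.9%, with 6 false calls. For the difference of effects (16101 genes), recovery was 6%, 36.4% and 63.1% with 0 false calls, and with the block 28.4%, 60.6% and 78.5% with 11 false calls.

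Alternatives were other scaling (size factors by median of ratios, library totals alone), no filter or a stricter filter (1 CPM and a total of 50 counts), the block, a fit of the compared groups only, DESeq2 with and without the block, limma voom, each library and each donor left out, and, for lists, an estimated correlation and fry. Alternatives added after the data were seen used the mean or the lowest of a gene's transcripts, counts thinned to the smallest library, the block without each donor for the difference of effects, and the score of other cell types added to the block. For comparisons that share libraries, 20 simulations with no changed gene gave the correlation that sharing alone produces. For the splits, 10 splits of 3 against 3 libraries were all run, and 100 were drawn for the difference of effects.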

Results

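RNA was sequenced from peripheral blood B cells of 3 donors, cultured for 24 h in 5 conditions, which gave 15 libraries. Cells of each donor were left unstimulated with vehicle (DMSO), with an inhibitor of Bruton's tyrosine kinase (BTKi), a kinase that relays signals of the B cell antigen receptor (BCR), or with an inhibitor of glycogen synthase kinase 3 (GSK3i). Cells of the same donors were also stimulated with an antibody against the BCR (anti-BCR), with vehicle or with BTKi. Each inhibitor was given at 1 µM, 30 minutes before the stimulus. Replicate numbers stand for donors, so n = 3 in each group.

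Totals of read counts, after 1 transcript was kept per gene, were 10.86, 16.68 and 17.67 M in the 3 unstimulated vehicle libraries and 15.84, 16.97 and 15.59 M with BTKi. Unstimulated GSK3i libraries held 21.16, 17.3 and 22.11 M. Anti-BCR libraries held 21.05, 23.14 and 24.59 M with vehicle and 17.03, 19.61 and 16.56 M with BTKi. Unstimulated vehicle replicate 1 was the smallest library. In a principal component analysis, the first component carried 41.2% of the variance, and on it anti-BCR vehicle replicate 2 stood at 98, apart from replicates 1 and 3 of its group at 43.4 and 52.6. A score of other cell types was the mean standardised log2 level of 52 markers of T cells, NK cells, monocytes and dendritic cells, plasmacytoid dendritic cells, and platelets and erythroid cells. It was 0.36, 0 and -0.35 in the unstimulated vehicle libraries, 0.77, 0.24 and -0.14 with BTKi, and 0.31, -0.11 and -0.34 with GSK3i. In the anti-BCR libraries it was -0.21, -0.83 and -0.6 with vehicle and 0.73, 0.16 and 0.01 with BTKi. All fold changes below are on the log2 scale with their standard error (SE). Adjusted p values of genes come from edgeR and those of gene lists from camera, and every gene named as changed moved the same way in 3 of 3 donors.

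The first comparison asked what BTKi did to B cells without a stimulus. TNFRSF9 (NM_001561), which encodes the costimulatory receptor 4-1BB, fell by 5.07 ± 0.76 (n = 3, adjusted p = 0.00203). CCL22 (NM_002990), a chemokine that attracts T cells, fell by 4.93 ± 0.66 (adjusted p = 0.00118). Its mean went from 242 ± 142 to 7.96 ± 2.94 counts per M (CPM, with SD, n = 3). The chemokines CCL4 and CCL3 fell by 3.87 ± 0.67 and 3.55 ± 0.55, and PYCR1 (NM_006907), an enzyme of proline synthesis, fell by 3.51 ± 0.49 (adjusted p = 0.00128). F5, which encodes coagulation factor V, fell by 3.76 ± 0.34 (adjusted p = 5.83e-05). IGSF3, a membrane protein of the immunoglobulin superfamily, and KCTD15 completed the 8 largest decreases, at -4.22 ± 0.61 and -3.43 ± 0.71. Among the largest increases were ABCG1 (NM_207174), a cholesterol exporter, at 2.17 ± 0.44 (adjusted p = 0.00796), and ACSM1, an acyl-CoA synthetase, at 1.59 ± 0.32.

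Growth and biosynthesis genes fell as groups in these unstimulated cells. Of 37 ribosome biogenesis and MYC target genes, 34 fell and none rose (36 adjusted over the list alone, camera adjusted p = 5.02e-37), with the chaperonin subunits HSPD1 at -1.35 ± 0.17 and HSPE1 at -1.38 ± 0.21. Their call was lost with an estimated correlation between genes (adjusted p = 0.0607 with an estimated correlation). Of 27 genes of amino acid transport and one-carbon metabolism, 16 fell (21 adjusted over the list alone, camera adjusted p = 1.01e-28). They were led by PSAT1, an enzyme of serine synthesis, at -2.99 ± 0.22 and SHMT2, which passes carbon units from serine to folate, at -1.36 ± 0.12. Of 19 ATF4 integrated stress response genes, 13 fell (17 adjusted over the list alone, camera adjusted p = 2.94e-21), among them the aminoacyl-tRNA synthetase genes AARS (-0.96 ± 0.09) and GARS (-1.38 ± 0.14). Of 24 glycolysis genes, 11 fell and 2 rose (12 and 4 adjusted over the list alone, camera adjusted p = 1.22e-06), with GAPDH at -1.16 ± 0.13 and PKM at -1.6 ± 0.18. The calls of these last 3 lists held with an estimated correlation but not with the donor as a block as well (adjusted p = 0.0634, 0.0634 and 0.0842). Of 77 nuclear-encoded oxidative phosphorylation genes, 24 fell (42 adjusted over the list alone, camera adjusted p = 5.31e-17, adjusted p = 0.183 with an estimated correlation).

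Signalling and activation lists fell as well. Of 31 immediate early and BCR-induced transcription factor genes, 12 fell and 1 rose (19 and 2 adjusted over the list alone, camera adjusted p = 2.01e-11); BATF3, an AP-1 family factor, stood at -3.7 ± 0.28 and EGR2 at -2.72 ± 0.41. Of 27 NF-kB target genes, 13 fell and 1 rose (16 and 1 adjusted over the list alone, camera adjusted p = 1.82e-12), with TNFAIP3, a feedback inhibitor of NF-kB, at -1.35 ± 0.14 and TRAF1 at -2.19 ± 0.25. Activation and costimulation markers (9 of 25 lower, 9 adjusted over the list alone, camera adjusted p = 1.31e-06) and cytokines and chemokines (10 of 24 lower and 2 higher, 10 and 3 adjusted over the list alone, camera adjusted p = 0.000611) also fell. Of 19 heat shock and stress genes, a list written as a sign of RNA and cell quality, 7 fell (7 adjusted over the list alone, camera adjusted p = 6.62e-08), led by the chaperone HSP90AB1 at -1.86 ± 0.18. Cell cycle and DNA replication genes fell, 7 of 39 (7 adjusted over the list alone, camera adjusted p = 0.00215), with the cyclin gene CCND2 at -2.27 ± 0.3. FOXO and quiescence genes rose, 8 of 30 (9 adjusted over the list alone, camera adjusted p = 6.91e-06, adjusted p = 0.13 with an estimated correlation). Among them were ZFP36L2, which promotes decay of mRNA, at 1.08 ± 0.18 and S1PR1, a receptor for egress from lymphoid tissue, at 0.96 ± 0.19. The calls of the 6 lists that fell held with an estimated correlation. With the donor as a block as well, that of the activation markers held (adjusted p = 0.00398), and those of immediate early genes (0.0634), NF-kB targets (0.0666), cytokines (0.0666), heat shock (0.0994) and cell cycle genes (0.0994) were lost.

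Further lists were called, and all of these calls were lost with an estimated correlation. Cholesterol and fatty acid synthesis had 11 of 31 genes lower (15 adjusted over the list alone, camera adjusted p = 1.03e-08, adjusted p = 0.172 with an estimated correlation). Endoplasmic reticulum chaperones had 9 of 21 lower and 1 higher (13 and 1 adjusted over the list alone, camera adjusted p = 1.37e-08, adjusted p = 0.183 with an estimated correlation), led by CALR at -1.21 ± 0.21. Mitochondrial biogenesis genes fell, 10 of 28 (12 and 1 adjusted over the list alone, camera adjusted p = 5.79e-06, adjusted p = 0.183 with an estimated correlation). TCA cycle genes fell, 7 of 27 (10 and 1 adjusted over the list alone, camera adjusted p = 0.000125, adjusted p = 0.204 with an estimated correlation). Fatty acid oxidation genes fell, 4 of 21 (5 adjusted over the list alone, camera adjusted p = 0.0445, adjusted p = 0.0963 with an estimated correlation). Their call was lost with the donor as a block (adjusted p = 0.0635), library totals only (0.0665), thinned counts (0.0677), a stricter filter (0.0714) and the compared groups only (0.0997), and without vehicle replicate 1 (0.0739), vehicle replicate 3 (0.0725) or BTKi replicate 2 (0.0793). Interferon-stimulated genes rose, 1 of 30 (the same adjusted over the list alone, camera adjusted p = 0.0187, adjusted p = 0.481 with an estimated correlation). That call was lost without vehicle replicate 3 (0.174), BTKi replicate 1 (0.0551) or BTKi replicate 2 (0.0961). From vehicle to BTKi, the score of other cell types rose by 0.29 ± 0.11 (SD, n = 3 donors).

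In this comparison edgeR called 1533 of 16346 genes (433 higher, 1100 lower), of which 57 rose and 332 fell at least 2-fold; with the donor as a block it called 3765, including 1532 of the 1533. The block together with the score of other cell types, a setting chosen after the data were seen, left 1052. Over the genes called with the block, the score lowered the median fold change from 0.53 to 0.42, in the direction of the block fit, and made SE 1.32 times as large. Without the block or the score, the count was 693 without unstimulated vehicle replicate 2, 676 without vehicle replicate 3, 931 without BTKi replicate 1, 650 without BTKi replicate 2 and 59 without replicate 3 in every group. Of the 8 largest increases, CORO2B, SLC2A5, ZBTB16, LIX1, TLE2 and TMEM71 (1.58 to 2.45) lost their calls without BTKi replicate 2 (adjusted p 0.0646 to 0.191). The same 6 lost them without vehicle replicate 3 (0.0719 to 0.176), and some also without vehicle replicate 1 or 2 or BTKi replicate 1 or 3 (0.052 to 0.114). TNFRSF9, IGSF3 and KCTD15 lost their calls with limma voom (adjusted p = 0.0604, 0.0655 and 0.179). Transcripts of the inhibitor targets were not called (BTK 0.19 ± 0.14, adjusted p = 0.463; GSK3A -0.03 ± 0.11, adjusted p = 0.905; GSK3B 0.21 ± 0.08, adjusted p = 0.117).

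**Figure D1:**
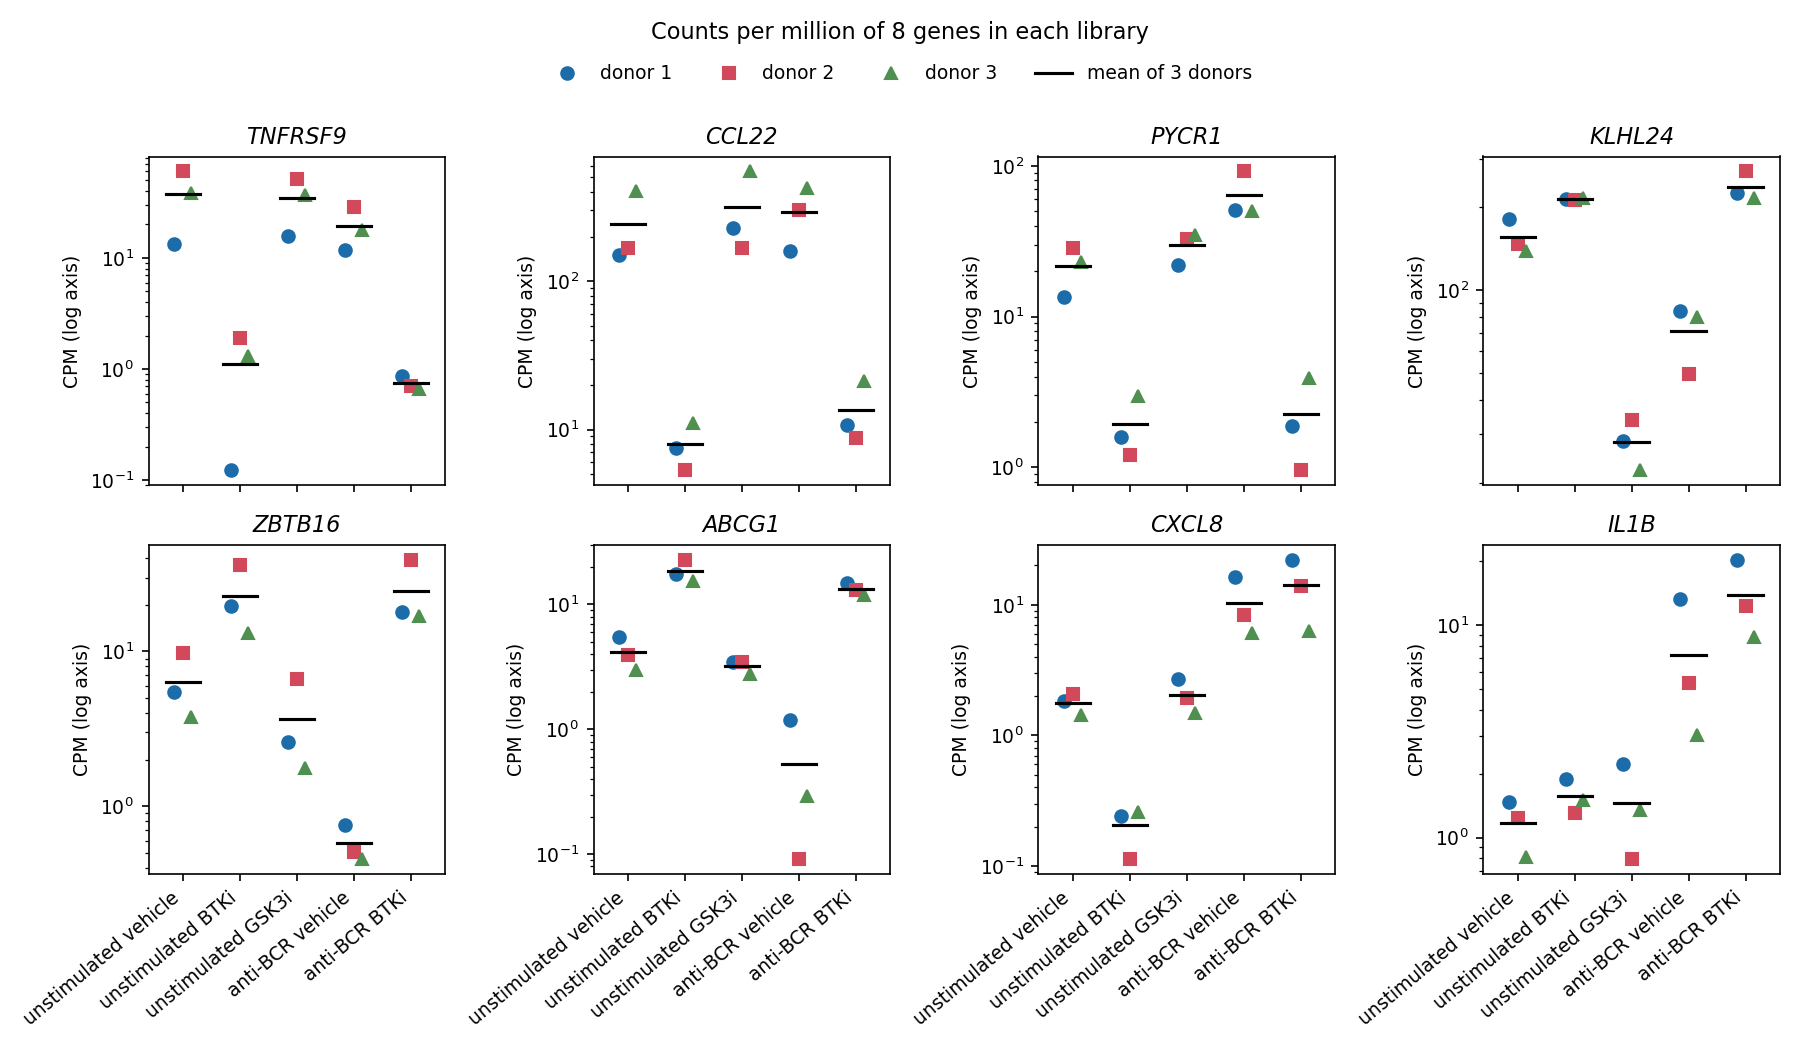
Level of 8 genes in each condition, in counts per M on a log axis, with 1 point per donor and a black line at the mean of 3 donors. CCL22 had a mean of 242 in unstimulated vehicle and 7.96 in unstimulated BTKi, and CXCL8 a mean of 0.206 in unstimulated BTKi and 14.1 in anti-BCR BTKi.

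GSK3i was compared with vehicle to show what inhibition of GSK3 did to unstimulated B cells. At least 2-fold, 112 of the called genes fell and 11 rose. KLHL24 (NM_017644), a substrate adaptor of a ubiquitin ligase, fell by 2.47 ± 0.2 (n = 3, adjusted p = 1.7e-05), ABTB1 fell by 2.77 ± 0.23 (adjusted p = 2.28e-05) and CCDC28A fell by 2.39 ± 0.18 (adjusted p = 8.14e-06). RMI2, a subunit of a complex that resolves DNA junctions, stood at -2.94 ± 0.33, FRAT1, a protein that binds GSK3, at -2.62 ± 0.28, and FBXO32, a ubiquitin ligase subunit under FOXO control, at -2.46 ± 0.29. RAPGEF3 and TCP11L2 were the remaining 2 of the 8 largest decreases (-2.39 ± 0.43 and -2.29 ± 0.27). MACC1 rose by 1.16 ± 0.18 (adjusted p = 0.00275). CCL2, a chemokine that attracts monocytes, stood at 4.59 ± 0.91 (adjusted p = 0.0128), with 5.03 ± 4.72 CPM against 0.209 ± 0.0833 (SD, n = 3).

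As groups, FOXO and quiescence genes fell, 7 of 30 (14 adjusted over the list alone, camera adjusted p = 9.09e-14, adjusted p = 0.147 with an estimated correlation). Next to KLHL24, the cell cycle inhibitor CDKN1B stood at -0.58 ± 0.09. Ribosome biogenesis and MYC targets rose as a list, 2 of 37 by single genes (19 adjusted over the list alone, camera adjusted p = 1.85e-17, adjusted p = 0.373 with an estimated correlation). Cholesterol and fatty acid synthesis genes rose, 2 of 31 (12 adjusted over the list alone, camera adjusted p = 4.69e-10, adjusted p = 0.373 with an estimated correlation). ATF4 integrated stress response genes rose, 1 of 19 (7 adjusted over the list alone, camera adjusted p = 4.48e-07, adjusted p = 0.373 with an estimated correlation). AARS stood at 0.48 ± 0.09. Lysosome and autophagy genes rose, 5 of 36 with 2 lower (9 and 2 adjusted over the list alone, camera adjusted p = 0.00051, adjusted p = 0.373 with an estimated correlation). The cathepsin gene CTSZ stood at 0.72 ± 0.08. CTSF, another lysosomal protease gene, fell by 4.86 ± 0.56 to 0.132 ± 0.0968 CPM (SD), and ULK1, a kinase that starts autophagy, fell by 1.58 ± 0.23.

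Further lists were called with few single genes, and none of their calls held with an estimated correlation. Amino acid transport and one-carbon metabolism rose with 0 of 27 genes called (0 adjusted over the list alone, camera adjusted p = 0.000139, adjusted p = 0.373 with an estimated correlation). Oxidative phosphorylation genes rose as a list, 1 of 77 (0 adjusted over the list alone, camera adjusted p = 3.12e-06, adjusted p = 0.764 with an estimated correlation). Endoplasmic reticulum chaperones rose as a list, 0 of 21 with 1 lower (1 and 1 adjusted over the list alone, camera adjusted p = 0.00324, adjusted p = 0.764 with an estimated correlation). The lower gene was the chaperone DNAJB9 at -0.84 ± 0.13. Glycolysis genes rose as a list, 1 of 24 (the same adjusted over the list alone, camera adjusted p = 0.00645, adjusted p = 0.373 with an estimated correlation). The glycolysis call was lost without GSK3i replicate 3 (0.0556). Mitochondrial biogenesis genes rose as a list, 2 of 28 with 1 lower (3 and 2 adjusted over the list alone, camera adjusted p = 0.0134, adjusted p = 0.764 with an estimated correlation). Without vehicle replicate 1 they lost their call (0.151). NF-kB target genes fell as a list, 1 of 27 (3 adjusted over the list alone, camera adjusted p = 0.0298, adjusted p = 0.649 with an estimated correlation). This call was lost without vehicle replicate 2 (0.0897) or 3 (0.127) or GSK3i replicate 1 (0.125) or 2 (0.0804). Of 18 Wnt and beta-catenin target genes none was called (0 adjusted over the list alone; median -0.07, camera adjusted p = 0.874); edgeR gave unadjusted p values under 0.05 to 2715 of all genes. Immediate early and BCR-induced transcription factor genes were not called as a list (camera adjusted p = 0.844), and their median of -0.07 and mean of 0.05 differed in sign.

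For GSK3i edgeR called 521 genes (98 higher, 423 lower), and 2144 with the donor as a block, including all 521. The count was 253 without vehicle replicate 1, 294 without vehicle replicate 2, 216 without GSK3i replicate 1, 339 without GSK3i replicate 2 and 209 without GSK3i replicate 3, and it was 48 and 36 without replicates 1 and 3 in every group. The 7 largest increases other than MACC1 (CCL2, FOSL2, WNT3, TUBA1C, DOK3, TEF and CDH23) each lost their call without at least 3 of the single libraries, each of the 6 libraries being among them (adjusted p 0.053 to 0.214). BTK (-0.02 ± 0.14, adjusted p = 0.975), GSK3A (0.15 ± 0.11, adjusted p = 0.56) and GSK3B (0.13 ± 0.08, adjusted p = 0.465) were not called.

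A direct comparison of GSK3i with BTKi in unstimulated cells, both at the same dose, tested the difference between the inhibitors. CCL22 and TNFRSF9 were higher with GSK3i by 5.31 ± 0.67 (n = 3, adjusted p = 0.000141) and 4.96 ± 0.76 (adjusted p = 0.00046). BATF3 was higher by 4.04 ± 0.28 (adjusted p = 1.02e-06), PYCR1 by 3.96 ± 0.49 and CCL2 by 4.74 ± 0.91. CTSF was lower by the log2 value -5.6 ± 0.56 (adjusted p = 1.35e-05), followed by TMEM71 (-3.29 ± 0.4), RMI2 (-3.26 ± 0.33), ABTB1 (-3.22 ± 0.23) and PNPLA7, a lysophospholipase gene (-3.22 ± 0.41).

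Biosynthesis lists were higher with GSK3i than with BTKi. All 37 ribosome biogenesis and MYC target genes were higher (37 adjusted over the list alone, camera adjusted p = 1.41e-39, adjusted p = 0.0657 with an estimated correlation). Amino acid transport and one-carbon metabolism genes were higher, 20 of 27 (the same adjusted over the list alone, camera adjusted p = 3.65e-21). ATF4 genes were higher, 17 of 19 (19 adjusted over the list alone, camera adjusted p = 5.84e-20). Both calls held with an estimated correlation, but not with the donor as a block as well (adjusted p = 0.0666 for each), with PSAT1 at 3.39 ± 0.22 and AARS at 1.44 ± 0.09. FOXO and quiescence genes were lower, 21 of 30 (24 adjusted over the list alone, camera adjusted p = 7.23e-13, adjusted p = 0.0657 with an estimated correlation), as was KLHL24 among them at -2.93 ± 0.2. Another 11 lists were called higher, and all 11 calls were lost with an estimated correlation (adjusted p 0.0657 to 0.235), although with the block as well that of the activation markers passed (0.0324). Their camera adjusted p ran from 1.45e-13 for cholesterol and fatty acid synthesis (22 of 31 higher, 24 adjusted over the list alone) to 0.00375 for cytokines and chemokines (10 of 24 higher and 3 lower, the same adjusted over the list alone). Interferon-stimulated genes were lower, 7 of 30 (7 adjusted over the list alone, camera adjusted p = 0.0191, adjusted p = 0.539 with an estimated correlation), a call lost without BTKi replicate 2 (0.0672) or GSK3i replicate 3 (0.102). In lists that were not called, signs differed between the median and mean of lysosome and autophagy genes (0.17 and -0.02, camera adjusted p = 0.187) and of plasmacytoid dendritic cell markers (-0.47 and 0.12, camera adjusted p = 0.893). With GSK3i, the score of other cell types was 0.34 ± 0.13 lower than with BTKi (SD, n = 3 donors).

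Between the inhibitors edgeR called 4985 genes (2690 higher and 2295 lower with GSK3i), with 716 and 657 at least 2-fold, and 7389 with the donor as a block. The block together with the score of other cell types left 3225, with a median fold change of 0.5 against 0.62 with the block alone and SE 1.46 times as large. Without the block or the score, the count was 1600 without replicate 3 in every group. BTK (-0.2 ± 0.14, adjusted p = 0.299), GSK3A (0.19 ± 0.11, adjusted p = 0.239) and GSK3B (-0.08 ± 0.08, adjusted p = 0.472) did not pass.

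The response to BCR stimulation was measured in vehicle-treated cells. CXCL8 (NM_000584), a chemokine that attracts neutrophils, rose by 2.52 ± 0.46 (n = 3, adjusted p = 0.00184). IL1B, an inflammatory cytokine, rose by 2.63 ± 0.54 (adjusted p = 0.00342), and IGSF3 and PDGFA, a growth factor, rose by 2.54 ± 0.46 and 2.32 ± 0.32. ZBTB16 (NM_006006), which encodes the transcriptional repressor PLZF, fell by 3.45 ± 0.65 (adjusted p = 0.00241), and LIX1 fell by 3.32 ± 0.49. TIMP3, an inhibitor of metalloproteinases, PDE3B, a cyclic nucleotide phosphodiesterase, and PDK4, which restrains pyruvate oxidation, stood at -3.22 ± 0.64, -2.79 ± 0.43 and -2.78 ± 0.42. NSUN7 (-3.15 ± 0.6), MGAT5B (-2.74 ± 0.65) and FAM111B (-2.65 ± 0.33) completed the 8 largest decreases, and CORO6 and SH2D5 were higher by 2.41 ± 0.48 and 2.41 ± 0.54.

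Every one of the 37 ribosome biogenesis and MYC target genes rose with the stimulus (37 adjusted over the list alone, camera adjusted p = 8.18e-28, adjusted p = 0.16 with an estimated correlation). HSPD1 stood at 1.32 ± 0.17 and NOP2 at 1.04 ± 0.16. Oxidative phosphorylation genes rose, 65 of 77 (69 adjusted over the list alone, camera adjusted p = 3.23e-27, adjusted p = 0.16 with an estimated correlation), for example UQCR11 at 0.82 ± 0.1. Glycolysis had 13 of 24 higher and 1 lower (13 and 2 adjusted over the list alone, camera adjusted p = 1.73e-07, adjusted p = 0.106 with an estimated correlation), with ALDOA at 1.08 ± 0.13. Cholesterol and fatty acid synthesis had 22 of 31 higher (25 adjusted over the list alone, camera adjusted p = 4.87e-11, adjusted p = 0.16 with an estimated correlation), with FASN, which makes fatty acids, at 1.56 ± 0.22. Genes of amino acid transport and one-carbon metabolism rose, 18 of 27 (20 adjusted over the list alone, camera adjusted p = 7.07e-11, adjusted p = 0.111 with an estimated correlation). ATF4 integrated stress response genes rose, 9 of 19 (11 adjusted over the list alone, camera adjusted p = 4.34e-09, adjusted p = 0.136 with an estimated correlation). Endoplasmic reticulum chaperones rose, 17 of 21 (19 and 1 adjusted over the list alone, camera adjusted p = 8.9e-10, adjusted p = 0.216 with an estimated correlation). FOXO and quiescence genes fell, 21 of 30 (23 adjusted over the list alone, camera adjusted p = 5.03e-14, adjusted p = 0.0895 with an estimated correlation), with the chemokine receptor gene CXCR4 at -2.27 ± 0.29 and S1PR1 at -1.63 ± 0.19.

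Heat shock genes rose, 10 of 19 (11 adjusted over the list alone, camera adjusted p = 1.34e-06, adjusted p = 0.111 with an estimated correlation). TCA cycle genes rose, 14 of 27 (17 and 1 adjusted over the list alone, camera adjusted p = 7.13e-06, adjusted p = 0.216 with an estimated correlation). Mitochondrial biogenesis genes rose, 16 of 28 with 3 lower (20 and 3 adjusted over the list alone, camera adjusted p = 1.34e-06, adjusted p = 0.216 with an estimated correlation). Interferon-stimulated genes fell, 10 of 30 (the same adjusted over the list alone, camera adjusted p = 0.00203, adjusted p = 0.429 with an estimated correlation). B cell identity and BCR signalling genes fell, 11 of 37 with 3 higher (11 and 4 adjusted over the list alone, camera adjusted p = 0.00795, adjusted p = 0.335 with an estimated correlation). CD79B, a signalling subunit of the BCR, stood at -0.59 ± 0.09. Lysosome and autophagy genes rose, 7 of 36 with 1 lower (the same adjusted over the list alone, camera adjusted p = 0.0427, adjusted p = 0.429 with an estimated correlation). Their call was lost without unstimulated vehicle replicate 1 (0.057) or 3 (0.1) or anti-BCR vehicle replicate 1 (0.0564) or 3 (0.0634), and with thinned counts (0.0792), library totals only (0.0581), a stricter filter (0.0711) or the transcript with the lowest total (0.0545). NF-kB targets were not called as a list at 24 h (6 higher and 2 lower of 27, the same adjusted over the list alone, camera adjusted p = 0.327). Immediate early genes (5 and 3 of 31, the same adjusted over the list alone, camera adjusted p = 0.531) and activation markers (2 and 1 of 25, the same adjusted over the list alone, camera adjusted p = 0.624) were not called. Cell cycle genes were not called either (9 and 2 of 39, the same adjusted over the list alone, camera adjusted p = 0.0509), but they were with the donor as a block (0.036), with fry (0.00125) and in other settings, such as no low-count filter (0.0154) or without unstimulated vehicle replicate 1 (0.0157) or anti-BCR vehicle replicate 3 (0.0445). Cytokines and chemokines were not called either (6 higher and 1 lower of 24, the same adjusted over the list alone, camera adjusted p = 0.251), and their median of -0.04 and mean of 0.23 differed in sign. The score of other cell types fell with these groups, by 0.55 ± 0.29 from unstimulated to anti-BCR vehicle (SD, n = 3 donors), and anti-BCR vehicle replicate 2, which stood apart, had the lowest score of all libraries (-0.83).

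For the stimulus edgeR called 4434 genes (2367 higher, 2067 lower), with 356 and 514 at least 2-fold, and 7015 with the donor as a block. The block together with the score of other cell types left 22, with a median fold change of 0.36 against 0.57 with the block alone and SE 2.01 times as large. Without either of them, the count was 2747 without unstimulated vehicle replicate 1, 2650 without anti-BCR vehicle replicate 2, and 2590, 2620 and 1910 without replicates 1, 2 and 3 in every group. HUNK (3.19 ± 0.96) and CD109 (2.77 ± 0.86), the 2 largest increases, lost their calls without unstimulated vehicle replicate 1 (adjusted p = 0.0961 and 0.117), unstimulated vehicle replicate 3 (0.0914 and 0.0972) or anti-BCR vehicle replicate 2 (0.169 and 0.176). BTK (-0.16 ± 0.14, adjusted p = 0.443), GSK3A (0.26 ± 0.11, adjusted p = 0.107) and GSK3B (-0.01 ± 0.08, adjusted p = 0.952) were not called.

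In stimulated cells, BTKi was compared with vehicle to show how much of the stimulated state it altered. LPL (NM_000237), the lipoprotein lipase gene, fell by 5.89 ± 0.51 (n = 3, adjusted p = 2.51e-06), F5 fell by 4.88 ± 0.34 (adjusted p = 1.13e-06) and PYCR1 fell by 4.85 ± 0.5 (adjusted p = 1e-05). TNFRSF9 fell by 4.7 ± 0.78, and LRRC32, which anchors latent TGF-beta at the cell surface, fell by 4.56 ± 0.27 (adjusted p = 3.82e-07). KCTD15 (-5.06 ± 0.73), IGSF3 (-5.05 ± 0.54) and the kinesin gene KIF1A (-4.68 ± 0.9) were also among the 8 largest decreases. ZBTB16 rose by 5.41 ± 0.66 (adjusted p = 3.35e-05), ABCG1 rose by 4.67 ± 0.52, and LIX1, NSUN7, NFAM1 and TCL1B rose by 4.15 ± 0.49, 3.77 ± 0.61, 3.89 ± 0.5 and 3.91 ± 0.48. NFAM1 encodes a receptor that signals through an ITAM motif, and TCL1B is a relative of the AKT coactivator TCL1A.

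Metabolic and growth lists were lower with BTKi in these stimulated cells. All 37 ribosome biogenesis and MYC target genes fell (37 adjusted over the list alone, camera adjusted p = 6.01e-40, adjusted p = 0.0912 with an estimated correlation; median -1.89), with HSPD1 at -2.62 ± 0.18. Oxidative phosphorylation had 72 of 77 lower and 1 higher (73 and 1 adjusted over the list alone, camera adjusted p = 4.25e-28, adjusted p = 0.133 with an estimated correlation), with UQCRQ at -1.68 ± 0.14. Genes of amino acid transport and one-carbon metabolism fell, 22 of 27 (22 and 1 adjusted over the list alone, camera adjusted p = 5.98e-19, adjusted p = 0.0659 with an estimated correlation). PSAT1 stood at -3.88 ± 0.22. ATF4 genes fell, 18 of 19 (the same adjusted over the list alone, camera adjusted p = 2.6e-12, adjusted p = 0.0659 with an estimated correlation). ASNS, which makes asparagine, stood at -1.9 ± 0.13. Endoplasmic reticulum chaperones fell, 19 of 21 with 1 higher (the same adjusted over the list alone, camera adjusted p = 1.06e-10, adjusted p = 0.175 with an estimated correlation). Cholesterol and fatty acid synthesis genes fell, 23 of 31 (the same adjusted over the list alone, camera adjusted p = 1.69e-09, adjusted p = 0.173 with an estimated correlation). Heat shock genes fell, 14 of 19 with 1 higher (the same adjusted over the list alone, camera adjusted p = 8.29e-08, adjusted p = 0.0659 with an estimated correlation). Mitochondrial biogenesis genes fell, 21 of 28 with 3 higher (22 and 3 adjusted over the list alone, camera adjusted p = 5.82e-08, adjusted p = 0.167 with an estimated correlation). Glycolysis genes fell, 14 of 24 with 4 higher (the same adjusted over the list alone, camera adjusted p = 6.65e-07, adjusted p = 0.0659 with an estimated correlation). TCA cycle genes fell, 18 of 27 with 3 higher (19 and 3 adjusted over the list alone, camera adjusted p = 1.41e-05, adjusted p = 0.186 with an estimated correlation).

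NF-kB targets fell, 17 of 27 with 2 higher (the same adjusted over the list alone, camera adjusted p = 9.18e-06, adjusted p = 0.108 with an estimated correlation), with NFKB1 at -2.07 ± 0.18. Immediate early genes fell, 17 of 31 with 4 higher (18 and 5 adjusted over the list alone, camera adjusted p = 0.000136, adjusted p = 0.127 with an estimated correlation). Activation markers fell, 12 of 25 with 1 higher (the same adjusted over the list alone, camera adjusted p = 0.00338, adjusted p = 0.175 with an estimated correlation, 0.0496 with the block as well). Cell cycle genes fell, 14 of 39 with 4 higher (the same adjusted over the list alone, camera adjusted p = 0.0232, adjusted p = 0.122 with an estimated correlation). BATF3 stood at -3.69 ± 0.25, the activation marker CD58 at -2.35 ± 0.3 and CCND2 at -3.37 ± 0.31. FOXO and quiescence genes rose, 22 of 30 (22 adjusted over the list alone, camera adjusted p = 1.06e-10, adjusted p = 0.0659 with an estimated correlation), with S1PR1 at 2.34 ± 0.2 and CXCR4 at 2.99 ± 0.3. Interferon-stimulated genes rose, 17 of 30 with 1 lower (18 and 1 adjusted over the list alone, camera adjusted p = 4.87e-05, adjusted p = 0.265 with an estimated correlation), with DDX58, a sensor of viral RNA, at 1.18 ± 0.14. B cell identity genes rose, 16 of 37 with 3 lower (the same adjusted over the list alone, camera adjusted p = 0.0167, adjusted p = 0.307 with an estimated correlation), a call lost without anti-BCR vehicle replicate 2 (0.0501). Cytokines and chemokines were not called (3 higher and 8 lower of 24, 5 and 8 adjusted over the list alone, camera adjusted p = 0.259), and their median of 0.29 and mean of -0.56 differed in sign. The score of other cell types rose with these groups, by 0.85 ± 0.2 from anti-BCR vehicle to anti-BCR BTKi (SD, n = 3 donors).

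In stimulated cells edgeR called 7460 genes (3720 higher, 3740 lower), with 1358 and 1417 at least 2-fold, and 9644 with the donor as a block. The block together with the score of other cell types left 136, with a median fold change of 0.44 against 0.73 with the block alone and SE 2.9 times as large. The median fold change of all genes was 0.09 (0.16 when libraries were scaled by their totals alone). Without the block or the score, the count was 4866 without replicate 3 in every group and 5994 without anti-BCR vehicle replicate 2. ZNF521 (4.3 ± 1.33) lost its call without anti-BCR vehicle replicate 1 (0.0571), 2 (0.0741) or 3 (0.0542) or BTKi replicate 2 (0.0912), and ADARB2 (4.07 ± 1.53) without any of those 4 (0.125, 0.145, 0.0598 and 0.0557) or BTKi replicate 3 (0.203). BTK was called at 0.41 ± 0.14 (adjusted p = 0.0245), a call lost without anti-BCR vehicle replicate 2 (0.0637) or 3 (0.0572) or BTKi replicate 1 (0.0544) or 2 (0.139). GSK3B was called at 0.21 ± 0.08 (adjusted p = 0.0415), a call lost without any of the 6 libraries (0.0505 to 0.138). GSK3A was not called (-0.21 ± 0.11, adjusted p = 0.136).

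**Figure D2:**
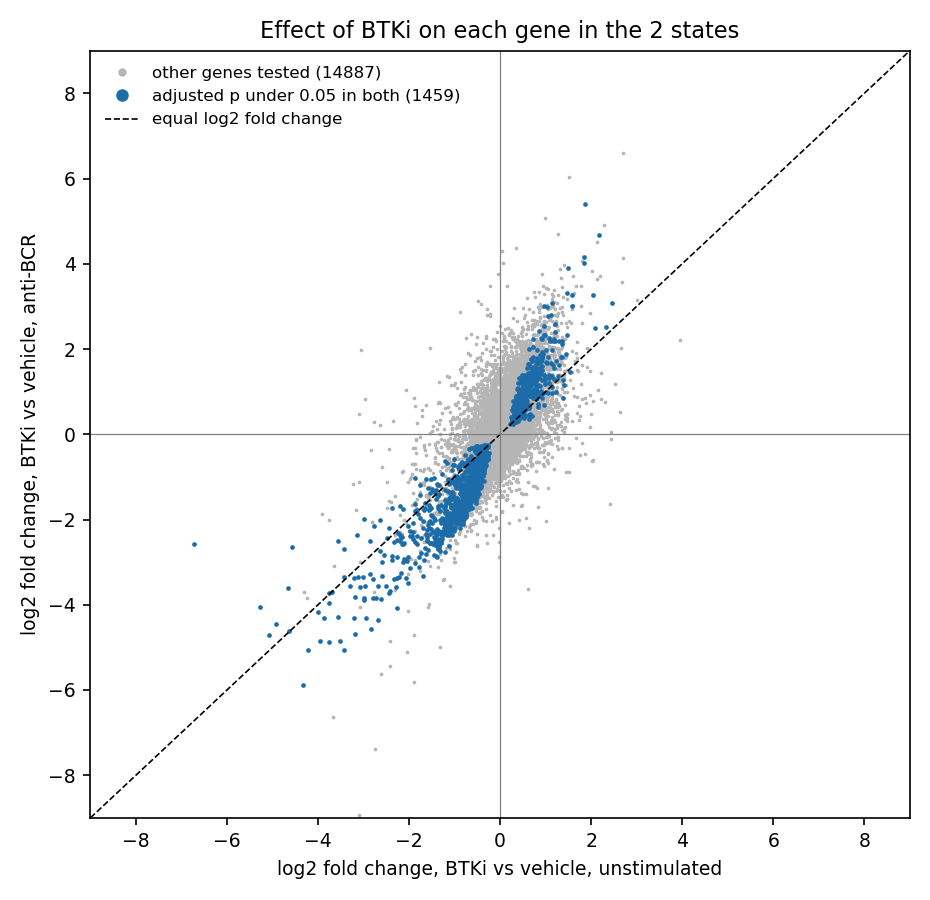
Log2 fold change of BTKi against vehicle in unstimulated cells (x axis) and in anti-BCR cells (y axis), with 1 point per gene, blue for the 1459 genes called in both states and grey for the 14887 others, and a dashed line where both are equal. All 1459 genes called in both moved the same way, and over all genes the correlation was 0.75.

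Fold changes of BTKi in the 2 states, which share no library, correlated at r = 0.75 across 16346 genes (rho 0.75, covariance 0.375; genes are not independent replicates). Of the called genes, 416 were higher in both states (98.5 expected from n1 × n2/N) and 1043 lower in both (251.7 expected), and 0 moved in opposite directions (99.1 and 250.3 expected; edgeR calls, genes with adjusted p under the threshold in both).

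The next comparison measured what the stimulus still did with BTKi present. CXCL8 rose by 6.07 ± 0.59 (n = 3, adjusted p = 0.00131), from 0.206 ± 0.0803 to 14.1 ± 7.9 CPM (SD, n = 3), and IL1B rose by 3.13 ± 0.53 (adjusted p = 0.0245). SLAMF7, a surface receptor of plasma cells and activated lymphocytes, rose by 1.76 ± 0.21 (adjusted p = 0.00475), and KCP and LRFN4 rose by 2.81 ± 0.44 and 1.53 ± 0.23. GLIPR1, CASK and the zinc finger genes ZNF92 and ZNF101 fell, by 0.55 ± 0.08, 0.53 ± 0.1, 0.75 ± 0.12 and 0.63 ± 0.11. As lists, cytokines and chemokines rose, 2 of 24 (2 and 1 adjusted over the list alone, camera adjusted p = 1.87e-05). Lysosome and autophagy genes rose, 2 of 36 (15 adjusted over the list alone, camera adjusted p = 1.56e-15). RRAGD, a GTPase of lysosomal nutrient sensing, stood at 1.43 ± 0.21 and CTSA at 0.74 ± 0.13. Both list calls held with an estimated correlation (adjusted p = 0.0166 for each), also with the donor as a block (0.0471 and 0.0261). ATF4 genes rose, 2 of 19 (4 adjusted over the list alone, camera adjusted p = 2.52e-07, adjusted p = 0.244 with an estimated correlation), the 2 being AARS at 0.66 ± 0.09 and PPP1R15A at 0.6 ± 0.09. Cholesterol and fatty acid synthesis genes rose as a list, 0 of 31 (the same adjusted over the list alone, camera adjusted p = 2e-05, adjusted p = 0.686 with an estimated correlation). Interferon-stimulated genes were not called (camera adjusted p = 0.0598), but they were with the donor as a block (0.00634), in a fit of these 6 libraries alone (0.0397) and without unstimulated BTKi replicate 1 (0.0253) or 2 (0.00435) or anti-BCR BTKi replicate 3 (0.00167).

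Amino acid transport genes rose as a list, 0 of 27 (1 adjusted over the list alone, camera adjusted p = 0.00786, adjusted p = 0.686 with an estimated correlation). Glycolysis genes rose as a list, 0 of 24 (2 and 1 adjusted over the list alone, camera adjusted p = 0.00985, adjusted p = 0.525 with an estimated correlation). FOXO genes fell as a list, 0 of 30 (the same adjusted over the list alone, camera adjusted p = 0.0166, adjusted p = 0.686 with an estimated correlation). These 3 list calls were lost without BTKi replicate 2 (0.25, 0.123 and 0.123), and also without anti-BCR BTKi replicate 1 (0.0537 for amino acid transport and 0.0656 for FOXO genes) or 3 (0.0782 for glycolysis). Ribosome biogenesis and MYC targets were not called (0 of 37, median 0.03, camera adjusted p = 0.421).

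With BTKi present edgeR called 50 genes (45 higher, 5 lower), with 21 and 1 at least 2-fold and unadjusted p under 0.05 for 1188, and 500 with the donor as a block. A fit of these 6 libraries alone called 0 (1255 with unadjusted p under 0.05). With all libraries, limma voom called 46 and DESeq2 178. The edgeR count was 7 without unstimulated BTKi replicate 1, 7 without replicate 2, 25 without replicate 3, 9 without anti-BCR BTKi replicate 2 and 25 without replicate 3. It was 0, 23 and 1 without replicates 1, 2 and 3 in every group. Of the named genes, CXCL8, SLAMF7 and AARS kept their calls with each single library left out in turn, but not in the fit of 6 libraries (adjusted p = 0.077, 0.111 and 0.111). CXCL8 and IL1B lost their calls with limma voom (adjusted p = 0.132 and 0.105). IL1B, KCP, LRFN4, ZNF92, ZNF101, GLIPR1, CASK, RRAGD, CTSA and PPP1R15A lost theirs without unstimulated BTKi replicate 2 and without anti-BCR BTKi replicate 2 (adjusted p 0.0713 to 0.208). Replicates 1 and 3 of both groups also ended some (0.0551 to 0.138). BTK, GSK3A and GSK3B were not called (0.07 ± 0.14, 0.08 ± 0.11 and -0.01 ± 0.08; adjusted p 0.993, 0.988 and 0.997).

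To size the response, genes called for the stimulus in vehicle with at least a 2-fold change were chosen for each donor in a fit without that donor (418 to 823 genes). In the donor left out, these genes moved by a median of 1.16 ± 0.43 with vehicle and 0.24 ± 0.12 with BTKi (SD, n = 3), so that 19.9% ± 3 of the response was kept. In each of the donors the share was 19.8%, 23% and 17%; 3 donors allow no permutation test to pass the threshold, so no p is given. Fold changes of the stimulus with vehicle and with BTKi, which share no library, correlated at r = 0.32 across genes (rho 0.31), with 27 genes higher in both (6.5 expected from n1 × n2/N) and 4 lower in both (0.6 expected).

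**Figure D3:**
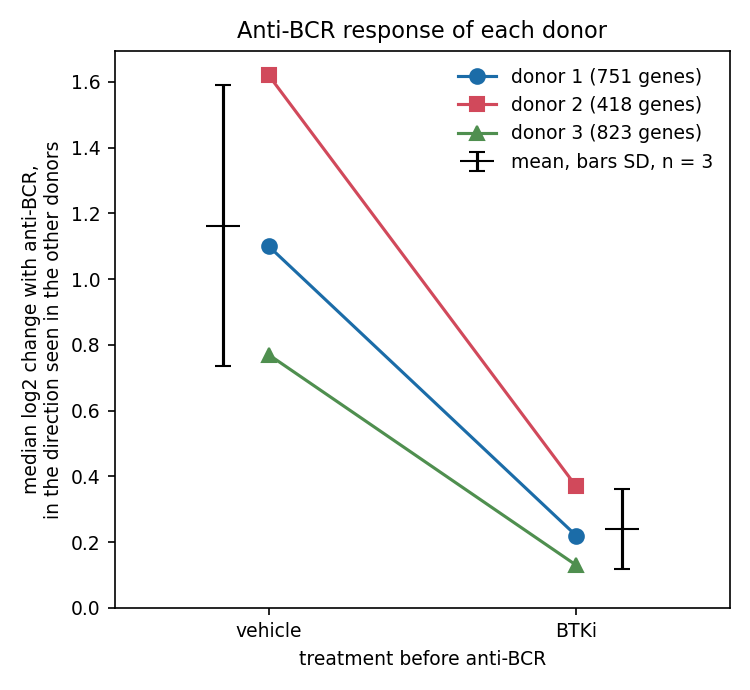
Median signed log2 change with anti-BCR over genes chosen without the donor shown, with vehicle and with BTKi, 1 line per donor (751, 418 and 823 genes) and black points for the mean with SD (n = 3). The mean was 1.16 with vehicle and 0.24 with BTKi, and every donor's line fell.

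The last comparison tested the difference itself between the effects of BTKi in stimulated and in unstimulated cells. No single gene passed with edgeR (smallest adjusted p = 0.0609), although 3539 had an unadjusted p under 0.05. The 5 genes with the smallest p did not pass (n = 3, adjusted p = 0.0609 for each). They were LMNB1, a nuclear lamin, at -1.2 ± 0.21, the proteasome subunit PSMD2 at -0.87 ± 0.15, the myristoyltransferase gene NMT2 at 1.36 ± 0.23, ARRDC2 at 1.5 ± 0.24 and MEGF6 at 2.06 ± 0.34. Other fits gave other counts: 3136 with the donor as a block (1616 higher, 1520 lower), 1554 by DESeq2, 3462 by DESeq2 with the block and 0 by limma voom. With the block, these 5 genes passed (adjusted p 0.00159 to 0.00538). The block together with the score of other cell types left 0 genes (1140 with an unadjusted p under 0.05).

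By list, ribosome biogenesis and MYC targets fell further with BTKi in stimulated cells, by a median of 1.02 (median -1.02; 0 of 37 genes called, 37 adjusted over the list alone, camera adjusted p = 2.15e-29, adjusted p = 0.203 with an estimated correlation). Oxidative phosphorylation genes fell as a list, 0 of 77 (median -0.55, 54 adjusted over the list alone, camera adjusted p = 1.03e-25, adjusted p = 0.24 with an estimated correlation). Amino acid transport genes fell as a list, 0 of 27 (median -0.65, 9 adjusted over the list alone, camera adjusted p = 1.04e-07, adjusted p = 0.203 with an estimated correlation). Endoplasmic reticulum chaperones fell as a list, 0 of 21 (median -0.77, 12 adjusted over the list alone, camera adjusted p = 8.57e-09, adjusted p = 0.356 with an estimated correlation). Mitochondrial biogenesis genes fell as a list, 0 of 28 (median -0.43, 10 and 2 adjusted over the list alone, camera adjusted p = 7.43e-07, adjusted p = 0.309 with an estimated correlation). Cholesterol and fatty acid synthesis genes fell as a list, 0 of 31 (median -0.39, 4 adjusted over the list alone, camera adjusted p = 1.65e-06, adjusted p = 0.356 with an estimated correlation). Glycolysis genes fell as a list, 0 of 24 (median -0.41, 10 adjusted over the list alone, camera adjusted p = 3.2e-05, adjusted p = 0.203 with an estimated correlation). Heat shock genes fell as a list, 0 of 19 (median -0.66, 5 adjusted over the list alone, camera adjusted p = 3.46e-05, adjusted p = 0.203 with an estimated correlation). TCA cycle genes fell as a list, 0 of 27 (median -0.26, 6 adjusted over the list alone, camera adjusted p = 0.000301, adjusted p = 0.356 with an estimated correlation). ATF4 genes fell as a list, 0 of 19 (median -0.43, 4 adjusted over the list alone, camera adjusted p = 0.000781, adjusted p = 0.356 with an estimated correlation).

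FOXO and quiescence genes rose as a list, 0 of 30 (median 0.7, 12 adjusted over the list alone, camera adjusted p = 9.7e-12, adjusted p = 0.203 with an estimated correlation). Interferon-stimulated genes rose as a list, 0 of 30 (median 0.74, 4 adjusted over the list alone, camera adjusted p = 6.74e-06, adjusted p = 0.356 with an estimated correlation). B cell identity genes rose as a list, 0 of 37 (median 0.33, 5 adjusted over the list alone, camera adjusted p = 0.0114, adjusted p = 0.374 with an estimated correlation). This last call was lost without anti-BCR vehicle replicate 2 (0.0564). The score of other cell types moved with these groups, its change with BTKi being 0.56 ± 0.18 larger in stimulated cells (SD, n = 3 donors). Without single libraries, edgeR called 1165 genes for this difference (without anti-BCR vehicle replicate 1), 144 (replicate 2), 561 (replicate 3) and 1 (without anti-BCR BTKi replicate 1), and 22 without replicate 2 in every group. BTK, GSK3A and GSK3B did not pass (0.23 ± 0.2, -0.18 ± 0.16 and 0 ± 0.11; adjusted p 0.548, 0.565 and 0.999).

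**Figure D4:**
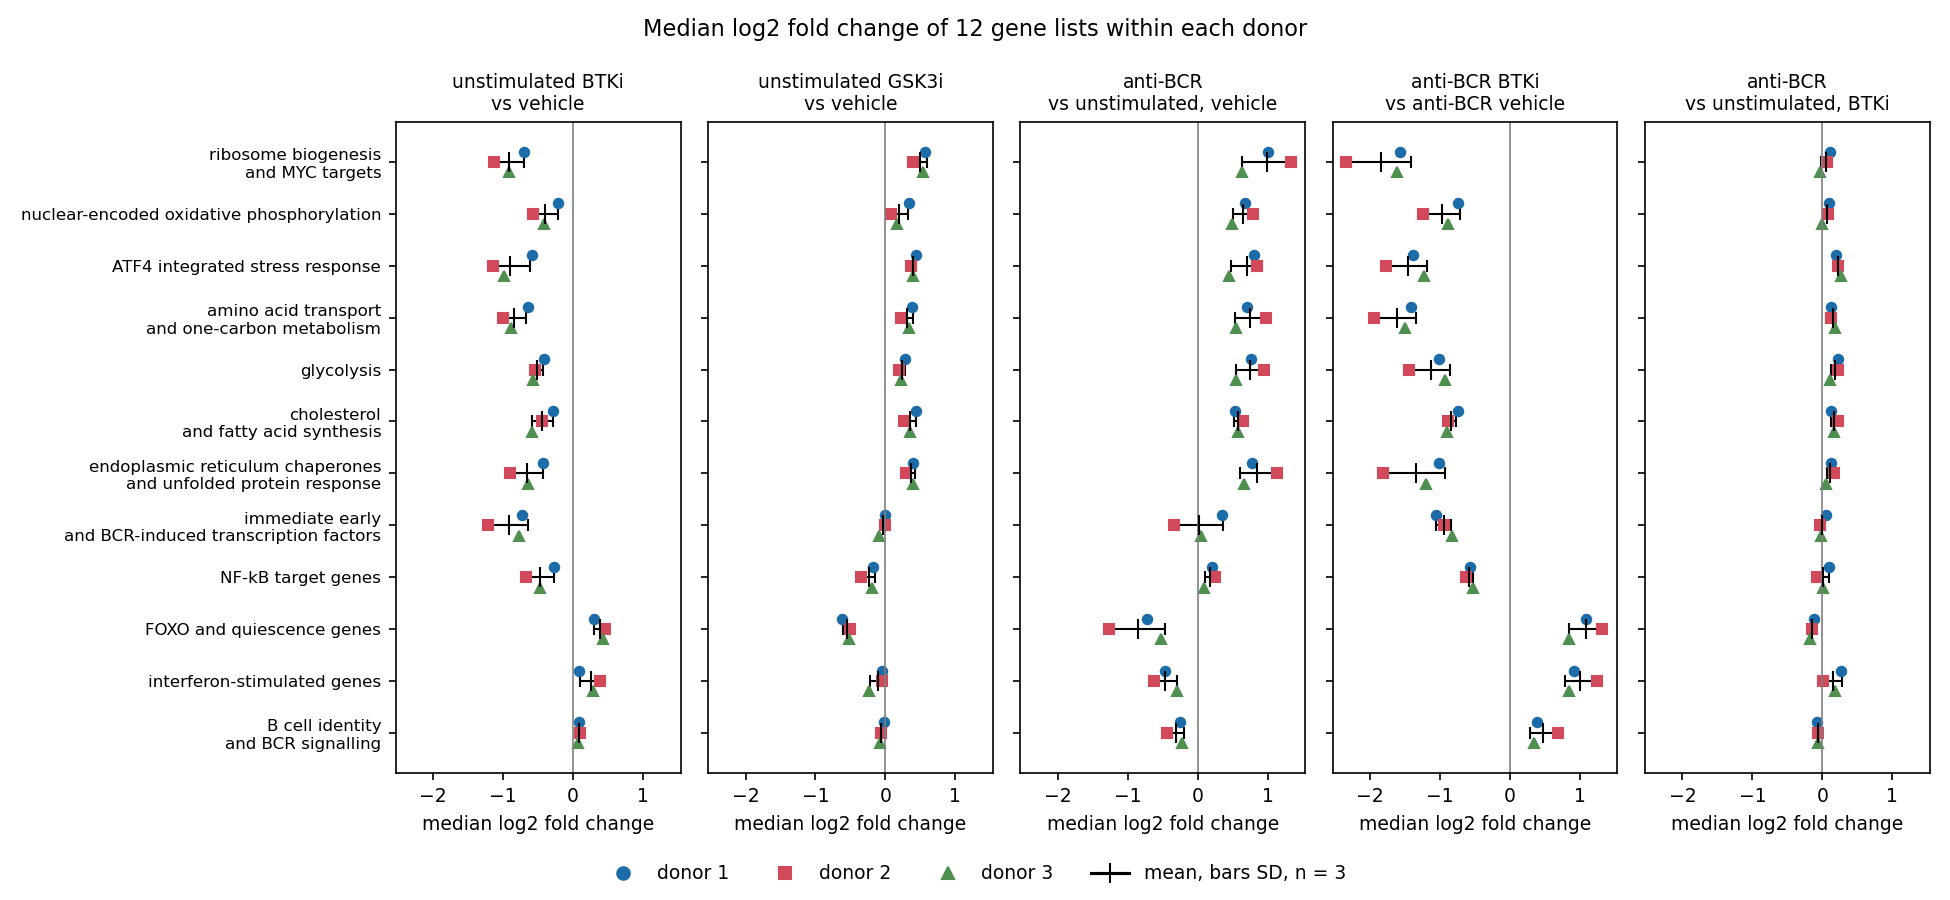
Median log2 fold change of 12 gene lists in 5 comparisons, with 1 point per donor and the mean with SD (n = 3). Ribosome biogenesis and MYC targets had means of donor medians of -0.92 with BTKi in unstimulated cells, 0.99 with anti-BCR and -1.85 with BTKi in anti-BCR cells.

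Comparisons that shared libraries were set against 20 simulations with no change in any gene, in which no gene was called in both. The stimulus and BTKi in stimulated cells correlated at r = -0.82 (covariance -0.474; simulated -0.46 and -0.0304), with 2174 genes higher with the stimulus and lower with BTKi (541.6 expected from n1 × n2/N) and 1870 the other way (470.4 expected). GSK3i and the stimulus correlated at 0.57 (0.155; simulated 0.54 and 0.0362), with 69 genes higher in both (14.2 expected) and 295 lower in both (53.5 expected). BTKi in unstimulated cells and the stimulus correlated at -0.44 (-0.151; simulated 0.53 and 0.0365), with 302 genes higher with BTKi and lower with the stimulus (54.8 expected) and 791 the other way (159.3 expected). BTKi and GSK3i in unstimulated cells correlated at -0.08 (-0.0189; simulated 0.52 and 0.0361), with 60 genes higher with BTKi and lower with GSK3i (11.2 expected) and 30 the other way (6.6 expected). A control group of 3 libraries cannot be split, so part of an excess of genes that move the way a shared control moves them may come from it.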

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

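The tests of library depth, of the share of B cells, of replicate 2 and of monocyte transcripts, and the count of splits, were chosen only after the result was seen. Results are given here because a test of the difference itself, between the effects of BTKi in anti-BCR and in unstimulated cells, called lists (camera), though none with an estimated correlation.

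By list (camera), the median log2 difference of the effects was -1.02 for ribosome biogenesis and MYC targets, -0.55 for oxidative phosphorylation, -0.77 for endoplasmic reticulum chaperones and -0.65 for amino acid transport and one-carbon metabolism. It was -0.43 for mitochondrial biogenesis, -0.39 for cholesterol and fatty acid synthesis, -0.41 for glycolysis, -0.66 for heat shock genes, -0.26 for the TCA cycle and -0.43 for ATF4 genes. It was 0.7 for FOXO and quiescence genes, 0.74 for interferon-stimulated genes and 0.33 for B cell identity genes. None of these 13 list calls held with an estimated correlation (smallest adjusted p = 0.203). By gene, edgeR called 3136 with the donor as a block and 0 without it.

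With BTKi in unstimulated cells, edgeR called 1100 of all genes lower, with a median of -0.72. With counts thinned to 10.86 M, the smallest library, their median stayed at -0.72, and edgeR called 1384 genes in all (1533 before). Thinning keeps each gene's expected share of its library, so the median could hardly move and does not test depth as a cause. The count shows only that most calls did not need unequal totals. After each library's trend with GC content and transcript length was removed, in the fit with the block, the median was -0.7 against -0.71 before, and 1092 of the 1100 were still called lower. B cell identity genes had a median of 0.12, where a smaller share of B cells alone would lower them. The means of donor medians were 0.09 ± 0.02 for them and -0.92 ± 0.22 for ribosome biogenesis genes (SD, n = 3). B cell identity genes also moved with anti-BCR under vehicle (-0.31 ± 0.11) and with BTKi in anti-BCR cells (0.47 ± 0.19). A response of these genes to the treatments could hide a change of share, so their median does not settle the share of B cells. With BTKi, the score of other cell types was 0.29 ± 0.11 (SD, n = 3) higher, and adding it to the block took the calls from 3765 to 1052 (median fold change in the direction of the block fit 0.53 to 0.42, SE 1.32 times as large), so other cell types stay open as part of the change, and an effect of the inhibitor on these genes stays a hypothesis, found and tested on the same data.

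Gene calls for the difference of effects appeared with the block. Without replicate 2, whose anti-BCR vehicle library stood apart, the block called 2338 genes, so calls of this kind also arose without that donor, while the block called 53 without replicate 1 and 835 without replicate 3; genes in common were not counted. Donor differences added to the spread (common dispersion 0.0504 without and 0.0112 with the block). Over the called genes, SE with the block were 0.8 of those without it, and absolute log2 fold changes were the same (median ratio 1). At the median, the calls thus came with a smaller error and not with larger differences. The SE ratio lay between the bounds set for this test, so how far donor differences account for the calls stays open. Adding the score of other cell types to the block left 0 genes (1140 at an unadjusted p under 0.05), with a median difference, in the direction of the block fit, of 0.41 against 0.68 and SE 1.57 times as large, so the call ended through both a smaller difference and a larger error. That score moves with the groups (its difference of effects was 0.56 ± 0.18, SD, n = 3), so the loss of calls cannot separate other cell types from the treatments. Some markers of other cells were at trace levels in anti-BCR vehicle and anti-BCR BTKi libraries (CD3E 0.326 ± 0.297 and 1.19 ± 0.688 CPM, CD14 0.191 ± 0.128 and 0.184 ± 0.202, S100A8 0 in both). Others were not, such as CD6 (11.5 ± 2.11 and 23.6 ± 9.89) and GNG11 (6.08 ± 1.86 and 2.67 ± 0.383), which moved in opposite directions. These levels do not give the share of other cells, so other cell types stay open as a source. An effect of BTKi that depends on the stimulus stays open as well.

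CXCL8 and IL1B were higher with anti-BCR in cells given BTKi. In the anti-BCR BTKi libraries, 6 monocyte markers together had 0.0841 ± 0.0351 (SD, n = 3) of the summed CPM of CXCL8 and IL1B. How much of these cytokines a stimulated monocyte holds per marker transcript is not in the data, so monocytes and B cells cannot be told apart as the source. The score of other cell types differed by 0.01 ± 0.12 between the 2 groups, and LYZ, the most abundant of the markers, had 4.73 ± 3.02 CPM in unstimulated and 1.64 ± 1.53 CPM in anti-BCR cells with BTKi.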

How the results depend on the processing

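The estimated correlation, fry, other tools, the block and the leave-outs were planned; the tests with the score of other cell types, thinned counts, other transcript choices and the block without a donor were chosen only after the result was seen. Of the 353 named gene calls, 0 reversed direction under any alternative. Of these calls, 50 were lost without at least 1 single library, 119 without 1 donor and 180 under at least 1 other setting. Most of the 180 were lost with the block and the score of other cell types (67 for anti-BCR, 65 for BTKi in anti-BCR cells and 17 for BTKi in unstimulated cells). Other settings ended 2, 4 and 8 calls there, 13 for anti-BCR under BTKi, 10 for GSK3i and 0 for GSK3i against BTKi. Other scaling, filters, transcript choices and thinning moved no count of called genes by over 1.5 times. With the donor as a block the counts of called genes were 3765 for BTKi in unstimulated cells, 2144 for GSK3i, 7015 for anti-BCR, 500 for anti-BCR under BTKi and 3136 for the difference of effects; the block ended the list call of fatty acid oxidation, added those of BCL2 family genes (adjusted p = 0.0454) with BTKi in unstimulated cells, cell cycle genes (0.036) with anti-BCR and interferon-stimulated genes (0.00634) with anti-BCR under BTKi, and changed no other list call. The smallest library held 10.86 M counts, and the self-test shows what that depth and 3 donors miss.

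DESeq2 called 958 genes for GSK3i, 178 for anti-BCR under BTKi and 1554 for the difference of effects, and with the block 3841 for BTKi in unstimulated cells, 2480, 6869 for anti-BCR, 752 and 3462. A fit of the compared groups only called 2246 genes for anti-BCR and 0 for anti-BCR under BTKi (edgeR; 1255 at an unadjusted p under 0.05, limma voom 46 with all libraries), where fewer libraries estimate the spread. For the difference of effects, the block called 53 genes without replicate 1, 2338 without replicate 2, 835 without replicate 3 and 2691 with thinned counts. With the block and the score of other cell types, edgeR called 1052 genes for BTKi in unstimulated cells, 2042 for GSK3i, 22 for anti-BCR, 136 for BTKi in anti-BCR cells, 635 for anti-BCR under BTKi, 3225 for GSK3i against BTKi and 0 for the difference of effects (1140 at an unadjusted p under 0.05); under this setting the list of platelet and erythroid markers turned direction for the difference of effects (BTKi effect, anti-BCR minus unstimulated (interaction): list platelet and erythroid markers, adjusted p = 0.0386), and its genes are part of that score. The same setting ended list calls of interferon-stimulated genes for BTKi in unstimulated cells (adjusted p = 0.373), anti-BCR (0.37) and GSK3i against BTKi (0.208), of B cell identity genes for anti-BCR (0.307), BTKi in anti-BCR cells (0.496) and the difference of effects (0.625), of cell cycle genes for BTKi in anti-BCR cells (0.121), and of TCA cycle (0.109) and ATF4 genes (0.312) for the difference of effects.

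Lists called with an estimated correlation were 9 for BTKi in unstimulated cells, 0 for GSK3i, 0 for anti-BCR, 0 for BTKi in anti-BCR cells, 2 for anti-BCR under BTKi, 0 for the difference of effects and 2 for GSK3i against BTKi; with the block as well they were 1, 0, 0, 1, 2, 0 and 1. Fry called 1 list for GSK3i, 26 for BTKi in anti-BCR cells, 2 for anti-BCR under BTKi and 6 for the difference of effects. With no filter 11 lists were called for anti-BCR under BTKi. The share of the anti-BCR response kept with BTKi was 28.5% over genes with at least a 4-fold response, 17.9% with no minimum and 18.4 to 21.4% without single donors. For each of these changes the cause was not tested, except where fewer samples were fitted.

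With each library and each donor left out in turn, called genes ranged from 59 (without replicate 3 in every group) to 1527 (without unstimulated vehicle replicate 1) for BTKi in unstimulated cells. For GSK3i the range was 36 (without replicate 3) to 608 (without replicate 2), for anti-BCR 1910 (without replicate 3) to 4585 (without anti-BCR vehicle replicate 1), and for BTKi in anti-BCR cells 4866 (without replicate 3) to 7324 (without anti-BCR vehicle replicate 1). For anti-BCR under BTKi it was 0 (without replicate 1) to 49 (without anti-BCR BTKi replicate 1), with 5 (without unstimulated BTKi replicate 2) to 13 lists (without unstimulated BTKi replicate 1). It was 0 to 1165 (without anti-BCR vehicle replicate 1) for the difference of effects, and 1600 (without replicate 3) to 4323 (without unstimulated GSK3i replicate 1) for GSK3i against BTKi.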

Other observations

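The correlation of GSK3i and BTKi effects from separate libraries was planned; the counts of splits were chosen only after the result was seen. Lists of other functions were not called by camera in any of the 7 comparisons with the main settings (TMM, the low-count filter and all 15 libraries, without the block). For BTKi in unstimulated cells, BCL2 family and apoptosis genes had 6 of 21 lower and 2 higher (median -0.02, adjusted p = 0.0519, with the donor as a block 0.0454), and plasma cell genes 4 of 20 lower and 1 higher (median -0.19, adjusted p = 0.0872). Under anti-BCR with vehicle, plasma cell genes had 6 of 20 higher (median 0.03, adjusted p = 0.116). With BTKi in anti-BCR cells, plasma cell genes had 7 of 20 lower and 2 higher (median -0.05, adjusted p = 0.198), BCL2 family genes 8 of 21 lower and 3 higher (median -0.23, adjusted p = 0.272) and antigen presentation genes 4 of 21 higher and 1 lower (median 0.22, adjusted p = 0.357). Wnt and beta-catenin target genes had 5 of 18 higher and 4 lower there (median -0.04, adjusted p = 0.926). The test fry, also without the block, did call some: BCL2 family genes for BTKi in unstimulated cells (adjusted p = 0.00123), in anti-BCR cells (0.000903) and for GSK3i against BTKi (0.00568), and plasma cell genes (0.0405) and antigen presentation genes (0.0365) for BTKi in anti-BCR cells. Camera called some in other settings without the block. For BTKi in unstimulated cells it did so with no filter (BCL2 family genes 0.0145, plasma cell genes 0.0273) and without replicate 1 in every group (0.0186 and 0.00255). For anti-BCR under BTKi it called plasma cell genes with library totals only (0.0467), and without unstimulated BTKi replicate 1 (0.00193) or anti-BCR BTKi replicate 2 (9.51e-05).

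Markers of other cell types were not called as lists by camera with the main settings. Under anti-BCR with vehicle, the medians were -0.75 for T cells (adjusted p = 0.211), -0.53 for NK cells (0.355), -0.84 for monocytes and dendritic cells (0.116), -0.14 for plasmacytoid dendritic cells (0.8) and -0.16 for platelets and erythroid cells (0.724). With BTKi in anti-BCR cells they were 0.99 (0.185), 0.53 (0.318), 1.38 (0.112), 0.35 (0.516) and 0.75 (0.357). There fry called the lists of T cells (adjusted p = 0.0318), monocytes and dendritic cells (0.0107) and platelets and erythroid cells (0.0371). With the donor as a block, fry also called T cells (0.00449), NK cells (0.0473) and monocytes and dendritic cells (3e-06) under anti-BCR with vehicle. In other settings camera called monocytes and dendritic cells for anti-BCR with vehicle (compared groups only, 0.00967). It also called them for BTKi in anti-BCR cells without anti-BCR BTKi replicate 3 (0.0491). For the difference of effects, it called T cells (0.0127) and monocytes and dendritic cells (0.0478) without unstimulated BTKi replicate 1. Heat shock and stress genes, a list written as a sign of RNA and cell quality, were called, with medians of -0.56 for BTKi in unstimulated cells, 0.75 for anti-BCR and -0.78 for BTKi in anti-BCR cells, so a difference in quality between these groups is not excluded. The tests of marker lists had few members with enough counts, so these p values do not show that the cell types were equally frequent.

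A hypothesis was that GSK3i and BTKi move genes in opposite directions. GSK3i against vehicle in unstimulated cells and BTKi against vehicle in anti-BCR cells share no library, and their fold changes correlated at -0.36 across 16346 genes (rho -0.44, covariance -0.142; genes are not independent replicates). Of the called genes, 61 rose with GSK3i and fell with BTKi (22.4 expected) and 317 the other way (96.3 expected). This goes with the hypothesis for cells in 2 different states, and no test of GSK3i in anti-BCR cells was possible.

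Splits of 3 against 3 libraries are too few for a share under 0.05. The real split called 1533 genes for BTKi in unstimulated cells, 521 for GSK3i, 4434 for anti-BCR, 7460 for BTKi in anti-BCR cells, 50 for anti-BCR under BTKi and 4985 for GSK3i against BTKi, and in each case 1 of 10 splits gave as many, with 0 genes as the highest other (edgeR). For lists, as many as the real split came from 2 of 10 splits (18 lists, highest other 18), 5 (11, 17), 3 (14, 16), 4 (17, 20), 5 (7, 9) and 4 (16, 18), in the same order. Donors pair the libraries, and among the other splits that part all 3 pairs the highest counts were 17, 10, 14, 20, 3 and 18 lists, in that order, and 0 genes in each comparison. For the difference of effects, the real split called 0 genes (edgeR, 3539 at an unadjusted p under 0.05), so all 100 of 100 splits gave at least as many (highest other 3688), and of the same splits 43 gave at least the real 13 lists (highest other 21). With the block and splits within donors, 5 of 100 gave at least 3136 genes (highest other 6150) and 59 at least 13 lists (highest other 22). New labels for the 12 libraries carry the effects of BTKi and of the stimulus into the difference, so neither set of splits tests chance for it, and whether chance gives such counts stays open.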
